A study of Danio rerio with 224 samples.

How the data were processed

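The series holds 224 RNA sequencing libraries from whole zebrafish (Danio rerio) embryos 5 days after fertilization. Per the labels' protocols, the fish carried a cmlc2 reporter transgene, polyadenylated RNA was selected, and stranded libraries were sequenced as single reads. Sample titles carry 1 of 2 prefixes, AL980 (132 libraries) or AM633 (92 libraries). Under each prefix there are DMSO controls and compounds named only by a short code, 11 codes under AL980 and 8 under AM633. Doses are in mg/kg, as the labels give them. The codes were not decoded, and no chemical identity or class is assumed. DMSO titles carry the number 0.005 or 0.01, whose meaning the labels do not state. The 0.005 title has 3 libraries under AL980 and 6 under AM633, and the 0.01 title has 3 under each. Each of 69 compound doses has 3 libraries, and 0.0005 mg/kg of the code Aci has 2. Groups, doses and replicate numbers came from the titles and dose labels alone. No label says whether libraries of a group came from separate clutches, so p-values measure only the spread between these samples.

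A table of expected counts (estimated reads per gene, which need not be whole) was deposited by the authors. Salmon 1.2.0, DESeq2 and the genome build GRCz11 are named in the submitters' processing notes, with no role or order, and how transcripts were summed to genes is not given in the sources used here. Of the values above 0, 34.6% were not whole, and all were rounded to whole counts before testing. The design was written for whole counts, and its test was kept. The table holds 37227 Ensembl gene identifiers, of which 29201 matched a symbol in the table of names supplied with the reference. Identifiers without a symbol held 3.33% of all counts and stayed in the library totals and tests. Zebrafish genes sharing a human-style symbol are printed with their identifiers. Duplicated genes and gene families such as the crystallins, globins, proteases and heat shock genes can share reads, so the split between copies is uncertain. No genome annotation was used, and no coordinates are given.

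The authors also deposited a table of log2-like variance-stabilised values for 26347 genes. Its file label states that genes were filtered and batches corrected, and the filter, the batch variable and the method are not given in the sources used here. In it, the mean of each gene was the same under both prefixes to within 1.4e-06, while in log2(CPM + 1) of the counts the median absolute difference between the prefixes was 0.128. A correction that sets the prefix means equal also removes real differences between the compounds under each prefix, so no compound was compared across prefixes, and this table served only as an alternative.

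Total counts ran from 8.22 to 23.6 M per library under AL980 (median 16.2 M) and from 14.3 to 31.7 M under AM633 (median 18.8 M). No 2 libraries of a group were copies of each other, since the smallest chi-square between any 2 was 3.92 per degree of freedom.

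For each compound, its dose groups and the DMSO groups of its own prefix were fitted together in edgeR 4.0.16 under R 4.3.3. Normalization was by TMM, and the filter was filterByExpr with a minimum count of 10 and a minimum total of 15, which left 23852 to 25158 genes. The quasi-likelihood test was run with robust dispersion, and the contrast was each dose minus the mean of both DMSO groups, weighted equally. P-values were adjusted by Benjamini-Hochberg within each contrast, and the threshold was 0.05. Standard errors (SE) of log2 changes were derived from the F statistic. CPM values are means over libraries with their standard deviation (SD). DNC with MDNC and Mes with Top, pairs of codes that share doses, were also compared directly at each shared dose in a fit of both codes, with 95% intervals. These tests, the gene lists and the rule for named genes were fixed before the data were examined. A contrast of the top dose minus the lowest dose of the same compound, in the same fit, and the pairwise comparison of lowest-dose groups were added after seeing the data.

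The genes named for a compound passed the adjusted threshold, had a mean of at least 5 CPM in the top dose or in DMSO, and had every top-dose library beyond every DMSO library of the prefix. Symbols that only name a clone were passed over. The 6 with the largest rise and the 6 with the largest fall were taken, plus up to 4 members of each gene list with the smallest adjusted p. The p53 target cdkn1a, CYP1A1 and CYP26A1 were followed at every dose. The same rule was applied to top minus lowest dose, and the text prints part of the genes taken.

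A set of 43 gene lists, covering stress and hormone responses, metabolism and markers of cell types, was written from general knowledge with 1093 entries, of which 49 found no gene. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and p-values were adjusted by Benjamini-Hochberg over all lists and compounds of a contrast. At the preset correlation 373 of 800 list tests passed for the top dose minus DMSO, 286 of 758 for the lowest dose minus DMSO and 285 of 758 for the top minus the lowest dose. With an estimated correlation the numbers were 0, 0 and 2.

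In counts simulated for 20000 mg/kg of HU against DMSO (24279 genes), edgeR made 2 false calls. It recovered 79% of 100 genes changed by a log2 of 1 and 100% of 100 changed by 2. For the top minus the lowest dose it recovered 70% and 96%, with 5 false calls. For 70 mg/kg of Pro (24448 genes) the shares were 91% and 97% against DMSO (14 false calls), and 85% and 94% against the lowest dose (7). DESeq2 made 20, 27, 29 and 22 false calls in these cases. The changed list was called each time, and camera at the preset correlation called 0 of 40 unchanged lists. This 0 and the false calls need not hold for real data, where genes may be correlated and spread unequal (HU, below).

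Alternatives were the DESeq2 1.42.0 Wald test, RLE size factors, no filter, all groups of a prefix in a single fit, only the top dose and DMSO libraries, either DMSO title alone, the replicate number as a block, limma on the deposited variance-stabilised table, an estimated list correlation, and leaving out each library in turn. Leaving out the DMSO 0.005 replicates 4 to 6 of AM633 together was added after seeing the data.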

Results

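Whole zebrafish embryos were sequenced after exposure to 19 coded compounds, 18 of them at 2 or more doses. Each dose was compared with DMSO of its title prefix. The 224 libraries form 74 groups, most of 3. In part of the compounds, genes of the exocrine pancreas, intestine, lens and photoreceptors fell, while p53 targets and chaperones rose in part. Foreign-compound metabolism was called up in 4 and down in 6 between top and lowest dose. With an estimated correlation between genes, 2 of the 285 list calls between the top and lowest dose held, and 0 of 373 against DMSO. A second layer of changes separated most compounds from DMSO at their lowest doses already.

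The DMSO titles carry the number 0.005 or 0.01, and the gene SLC5A1, an intestinal sugar transporter, was higher by a log2 of 0.80 ± 0.07 (SE) in the 0.01 libraries of AL980 (n = 3 and 3, edgeR adjusted p = 0.0093). It was among 44 genes that differed there, 35 higher and 9 lower of 23020 tested, with 2636 at unadjusted p < 0.05. HMOX1, which breaks down haem, was higher by 1.36 ± 0.17 (edgeR adjusted p = 0.034), and the scavenger receptor gene marco by 1.38 ± 0.20 (edgeR adjusted p = 0.048), both chosen after their values were seen. Under AM633 2 genes differed, GPNMB (-0.44 ± 0.05, edgeR adjusted p = 0.046) and ENSDARG00000113851 (-1.20 ± 0.12, edgeR adjusted p = 0.014), with 1914 at unadjusted p < 0.05. No gene passed edgeR for a difference of this contrast between the prefixes (0 of 24652, 2393 at unadjusted p < 0.05, 145 with DESeq2 and 0 with limma on the deposited table). With DESeq2 the 44 became 264 and the 2 became 100. They were 18 and 1 with limma on the deposited table, and 10 and 0 with the replicate number as a block. Without a filter the 2 became 1. These counts rest on single libraries. Under AL980 the 44 became 5, 0 or 2 without 0.005 replicate 1, 2 or 3, and 7 or 15 without 0.01 replicate 1 or 3. Under AM633 the 2 became 4, 1, 1 or 1 without 0.005 replicate 1, 4, 5 or 6, and 0 or 1 without 0.01 replicate 1 or 3. The 0 became 4 without the AL980 0.005 replicate 2, 2 without the AL980 0.01 replicate 3, 8 or 1 without the AM633 0.005 replicate 1 or 2, and 1, 15 or 3 without the AM633 0.01 replicate 1, 2 or 3. Of the 9 DMSO libraries of AM633, the 0.005 replicates 4, 5 and 6 stand apart, with the clock gene PER2 at 31.6, 41.4 and 47.2 CPM against at most 8.27 in the other 6, and FOS at 20.6 to 26.0 against 62.3 to 85.7. Of all 84 ways to set 3 of these libraries against 6, this one gave the most genes, 1346, and the labels give no reason for it. With these 3 left out, an alternative chosen after seeing the data, edgeR gave 0 genes between the titles of AM633 (1633 at unadjusted p < 0.05, where all libraries had given 100 with DESeq2 and 1 with limma) and 1 for the difference between the prefixes.

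PER2, a clock gene that light induces in zebrafish, stood at 17.4 ± 2.37 CPM (mean ± SD, n = 6) in the DMSO libraries of AL980, at 103 ± 6.72 at the lowest dose of FPB (n = 3) and at 113 ± 4.38 at its top dose (n = 3). The log2 change was 2.57 at 0.1 mg/kg (edgeR adjusted p = 3.1e-11) and 2.70 ± 0.09 at 1.2 mg/kg (edgeR adjusted p = 1.4e-11). The gene cry5 and the cryptochrome gene cry3b rose with it in FPB, by 2.83 ± 0.13 and 2.16 ± 0.08 at the top dose (edgeR adjusted p = 8e-10 and 7e-11), while the activity-dependent gene egr4 fell by 2.26 ± 0.21 (edgeR adjusted p = 1.2e-05). In all, 3628 genes changed at 1.2 mg/kg of FPB and 5331 at 0.1 mg/kg. Without replicate 1, 2 or 3 at 1.2 mg/kg the 3628 became 2384, 1865 or 1695, and with the 0.01 DMSO libraries alone 1545. As most compounds showed this pattern, a contrast of top minus lowest dose was added after seeing the data. It holds what differs between doses, handling included (PER2 in Top, log2 -3.54, may be such), and loses effects already full at the lowest dose.

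Against DMSO, between 3474 genes (Aci at 0.002 mg/kg) and 12851 genes (HU at 20000 mg/kg) changed at the top doses. At the lowest doses the counts ran from 6 (Aci) and 127 (HU) to 6800 (DNC) and 7778 (PHT). Between the top and lowest dose they ran from 0 in FPB, PHT, MDNC, CTZ and Cyh to 6215 in 5FU, 6299 in SAHA and 9864 in HU. In HU the counts grew with each dose, with 127, 338, 944, 2300 and 12851 genes from 1000 to 20000 mg/kg, and the first 4 were made up mostly of genes that rose (82.7% at 1000 mg/kg). Mes (369, 811, 1674 and 5515) and Top (184, 729, 1174 and 3743) also grew with each dose from 100 to 5000 mg/kg. So did Pro (4252, 5140, 6289 and 7514), Nit (5420, 6300 and 6599), Cyh (2034, 2652 and 4193) and Fen (2869, 4057 and 4377), though edgeR gave 4 genes between the top and lowest dose in Nit and 0 in Cyh (3165 at unadjusted p < 0.05, 246 with DESeq2, 0 with limma). The other codes with more than 1 dose did not grow at every step, such as DNC (6800, 6170 and 7072) and PHT (7778, 6679, 7252 and 6696). With the DMSO 0.005 replicates 4 to 6 of AM633 left out, the counts at the lowest dose became 235 for Aci, 1078 for Mes, 560 for Top and 3057 for Cyh (2034 with all libraries). Those at 0.0005 mg/kg of Aci, 500 mg/kg of Mes, and 500 and 1500 mg/kg of Top became 232, 1732, 1189 and 2003. Every other count of an AM633 compound against DMSO, or between its top and lowest dose, stayed within 1.5 times, and the direct comparisons of codes were not run this way. Leaving out libraries that stand apart also lowers the DMSO spread, and what part of these rises comes from that was not tested.

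**Figure D1:**
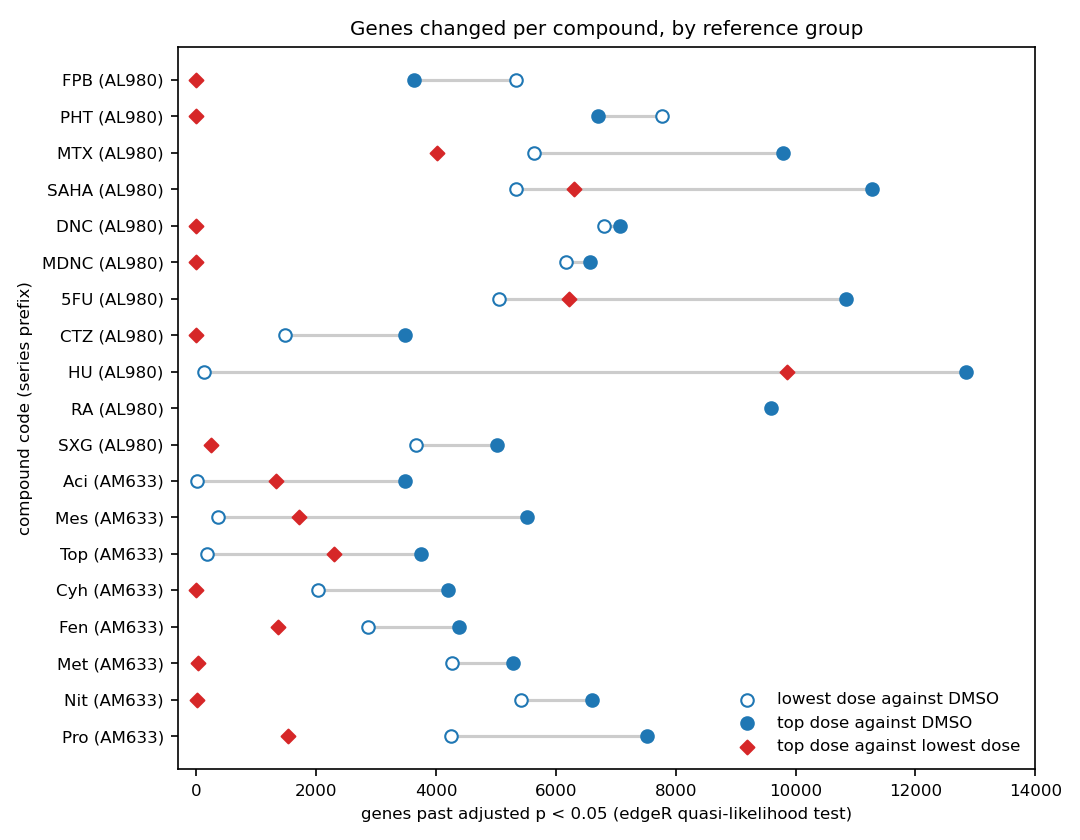
Genes past the edgeR threshold for each compound at the top dose against DMSO, at the lowest dose against DMSO and between the top and lowest dose, for example 12851, 127 and 9864 for HU and 6696, 7778 and 0 for PHT.

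Lowest-dose groups were also compared with each other within a prefix, in a fit added after seeing the data. DNC and MDNC, which differ from DMSO by 6211 and 5524 genes in that fit, differ from each other by 26. FPB and DNC differ by 79 genes, PHT and SAHA by 348 where each is 7687 and 6467 from DMSO, and Fen and Met by 15 where each is 3646 and 5012 from DMSO. Nit and Pro differ by 52. MTX and SXG stood apart from every other code, with 7356 genes between them. At the lowest dose of Aci 26 genes differ from DMSO, and 599 at that of HU. In SXG PER2 stood at 418 ± 19.8 CPM at 250 mg/kg and 427 ± 52.8 at 20000 mg/kg. No label names a collection batch, a clutch or an hour.

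**Figure D2:**
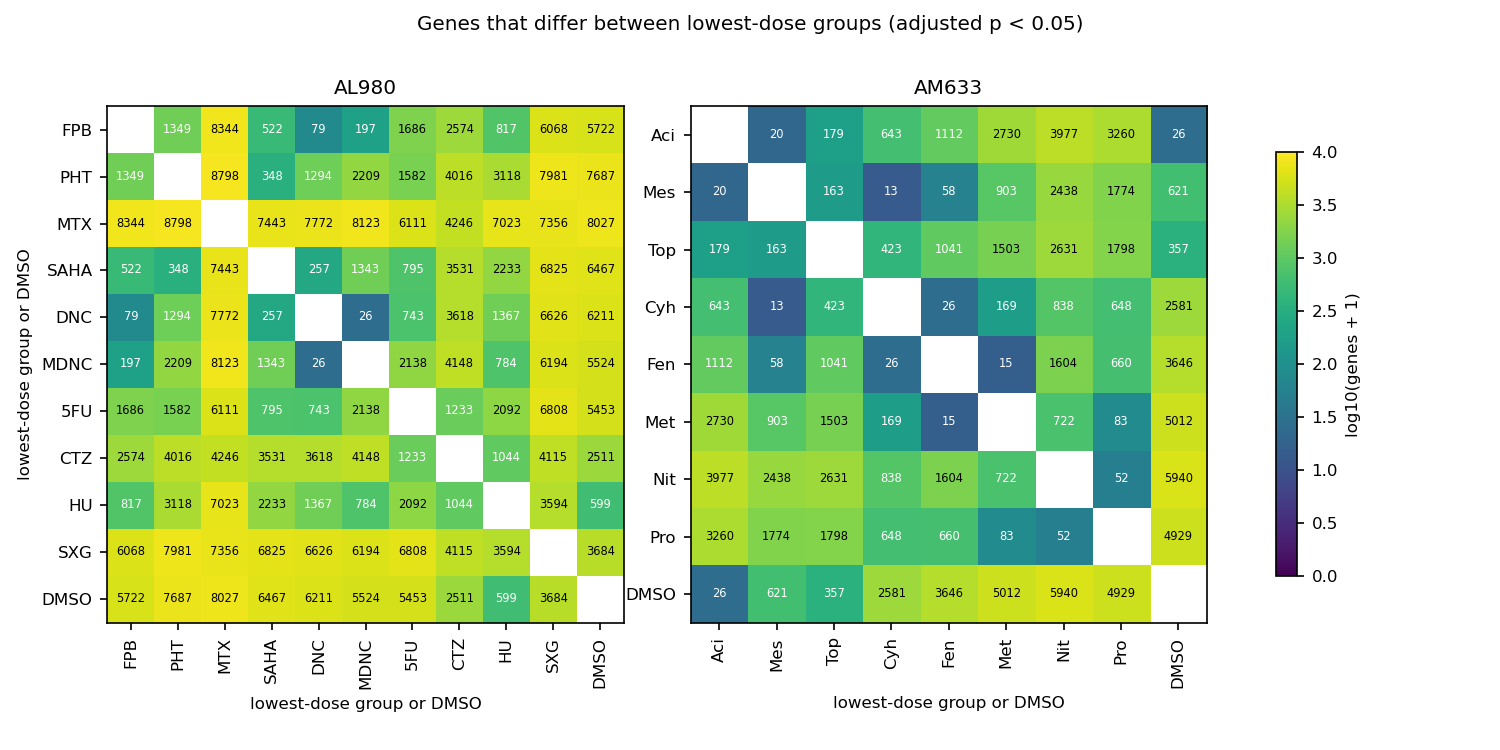
Genes that differ between the lowest-dose groups of each pair of compounds and between each and DMSO, under each prefix, such as 26 between DNC and MDNC and 6211 and 5524 between those and DMSO.

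MTX lowered digestive genes. The chymotrypsin gene ctrb.2 went from 85.0 ± 23.7 CPM at 10 mg/kg to 0.839 ± 0.534 at 300 mg/kg (n = 3 and 3, log2 -6.69 ± 0.47, edgeR adjusted p = 5.1e-07), against 171 ± 68.8 in DMSO (n = 6, log2 -7.68 ± 0.46, edgeR adjusted p = 2e-08). Elastase ela2 fell by 6.53 ± 0.45 and the chitinase chia.3 by 6.64 ± 0.52 (edgeR adjusted p = 4.9e-07 and 8.8e-07), and the intestinal sphingomyelinase ENPP7 (ENSDARG00000053526) by 6.71 ± 0.71 (edgeR adjusted p = 1.3e-05). Of 17 exocrine pancreas genes 16 fell from the lowest to the top dose (16 adjusted over the list alone, median log2 -4.80, camera adjusted p = 7.2e-28, adjusted p = 0.17 with an estimated correlation). Of 37 intestine genes 33 fell and 1 rose (33 and 1 adjusted over the list alone, median -3.14, camera adjusted p = 3.7e-28, adjusted p = 0.28 with an estimated correlation). The lens crystallins fell in 34 of 44 (39 adjusted over the list alone, median fall 1.00, camera adjusted p = 3e-22, adjusted p = 0.35 with an estimated correlation), from a median of 0.69 above DMSO at 10 mg/kg to -0.33 at 300 mg/kg. Of the cell cycle and DNA replication list, PCNA rose from 176 ± 26.8 to 307 ± 29.8 CPM (0.80 ± 0.12, edgeR adjusted p = 0.00025) and RRM2 (ENSDARG00000078069) by 1.45 ± 0.23 (edgeR adjusted p = 0.00046). In that list 18 of 25 rose (20 adjusted over the list alone, median 0.59, camera adjusted p = 1.1e-11, adjusted p = 0.38 with an estimated correlation). The chaperone gene hspa1b rose by 1.70 ± 0.23 (edgeR adjusted p = 7.6e-05). Of 26 heat shock genes 14 rose (18 adjusted over the list alone, median 0.68, camera adjusted p = 3.2e-09, adjusted p = 0.31 with an estimated correlation). With these lists moved the mitochondrial share of counts, at 3.83% to 4.47% at 300 mg/kg against 3.05% to 3.28% at 10 mg/kg, and the share of the 10 most abundant genes, at 15.8% to 17.5% against 13.2% to 13.8%. In all 4009 genes changed between 10 and 300 mg/kg of MTX, 1939 up and 2070 down, and 9783 changed at 300 mg/kg against DMSO. Replicate 2 at 300 mg/kg stands apart, with a chi-square per degree of freedom of 25.6 and 28.5 to the other libraries of its group against 8.21 between those, and the highest mitochondrial share. So does replicate 3 at 10 mg/kg of MTX, with 18.5 and 18.0 against 5.70. Fitted to the libraries of those 2 doses alone, the 4009 became 1019.

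In SAHA the ferritin-like gene fthl29 went from 2.74 ± 0.481 CPM at 50 mg/kg to 33.8 ± 5.90 at 1000 mg/kg (n = 3 and 3, log2 3.62 ± 0.26, edgeR adjusted p = 4.2e-07). STC1 (ENSDARG00000058476), which codes for the calcium hormone stanniocalcin, went from 11.3 ± 1.68 to 0.517 ± 0.240 (-4.38 ± 0.25, edgeR adjusted p = 1.9e-08), and the calcium-binding parvalbumin gene pvalb5 fell by 2.83 ± 0.18 (edgeR adjusted p = 5.9e-08). The epithelial transcription factor gene ELF3 rose from 14.4 ± 4.72 to 82.6 ± 16.6 CPM (edgeR adjusted p = 1.7e-05), and by 3.05 ± 0.20 from DMSO (edgeR adjusted p = 3.6e-08). POLR1C, a subunit of RNA polymerase I and III, fell by 1.62 ± 0.20 (edgeR adjusted p = 6.7e-05). Of 28 ribosome biogenesis genes 22 fell (27 adjusted over the list alone, median -0.49, camera adjusted p = 1.9e-13, adjusted p = 0.28 with an estimated correlation), from a median of 0.32 above DMSO at 50 mg/kg to -0.17 at 1000 mg/kg. CYP1A1 rose by 1.38 ± 0.22 (edgeR adjusted p = 0.00058). It was among 10 of 14 genes of the aryl hydrocarbon receptor battery that rose (10 adjusted over the list alone, median 0.91, camera adjusted p = 3.7e-05, adjusted p = 0.23 with an estimated correlation). Matrix genes rose in 20 of 34 (22 up and 1 down adjusted over the list alone, median 0.57, camera adjusted p = 1.8e-09, adjusted p = 0.32 with an estimated correlation), LUM by 0.80 ± 0.08 (edgeR adjusted p = 7e-06). The share of the 10 most abundant genes moved with these lists, from 11.3% in each library at 50 mg/kg to between 10.3% and 10.9% at 1000 mg/kg. Between 50 and 1000 mg/kg of SAHA 6299 genes changed, 3459 up and 2840 down. Without replicate 1 at 1000 mg/kg the count was 4053, and from the libraries of both doses alone it was 3673.

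The p53 target mdm2 went from 13.2 ± 2.51 CPM at 1000 mg/kg of 5FU to 106 ± 8.52 at 30000 mg/kg (n = 3 and 3, log2 3.01 ± 0.18, edgeR adjusted p = 1.5e-08), with DMSO at 13.3 ± 1.92 (n = 6). CCNG1 went from 366 ± 7.87 to 1560 ± 165 (2.09 ± 0.12, edgeR adjusted p = 3.2e-09). The gene casp8, which starts apoptosis, rose by 2.29 ± 0.20 (edgeR adjusted p = 5.2e-07) and cdkn1a by 1.26 ± 0.11 (edgeR adjusted p = 5.5e-07). Of 24 p53 targets 16 rose (16 adjusted over the list alone, median 0.92, camera adjusted p = 3.7e-13), and this call held at adjusted p = 0.039 with an estimated correlation. Photoreceptor genes fell in 40 of 47 and rose in 1 (42 and 2 adjusted over the list alone, median -1.33, camera adjusted p = 1.1e-26, adjusted p = 0.24 with an estimated correlation). The red cone opsin gene opn1lw2 went from 825 ± 32.5 to 179 ± 38.7 CPM (-2.20 ± 0.15, edgeR adjusted p = 6.7e-08). The phospholipase gene PLA2G1B went from 18.4 ± 5.32 to 1.05 ± 0.268 (-4.13 ± 0.45, edgeR adjusted p = 8e-06). With it 17 of 18 exocrine pancreas genes fell (18 adjusted over the list alone, median -2.20, camera adjusted p = 1.5e-14, adjusted p = 0.34 with an estimated correlation), from a median of 0.62 above DMSO to -1.46. Of the cell cycle and DNA replication list CDK1 rose by 1.21 ± 0.11 (edgeR adjusted p = 6.6e-07), and 17 of 25 genes in all (18 adjusted over the list alone, median 0.76, camera adjusted p = 2.2e-11, adjusted p = 0.38 with an estimated correlation), from -0.16 against DMSO to 0.53. The interferon-induced gene isg15 rose by 3.34 ± 0.39 (edgeR adjusted p = 8.1e-06). Along with these lists the mitochondrial share of counts was 3.36% to 3.85% at 30000 mg/kg against 2.69% to 3.25% at 1000 mg/kg, and that of the 10 most abundant genes 14.7% to 15.3% against 12.3% to 12.7%. In all 6215 genes changed between both doses of 5FU, 3047 up and 3168 down, or 4079 without replicate 1 at 30000 mg/kg.

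HU at 20000 mg/kg raised stress genes of several kinds. The endoplasmic reticulum chaperone gene HYOU1 went from 35.4 ± 3.06 CPM at 1000 mg/kg to 127 ± 21.5 (n = 3 and 3, log2 1.84 ± 0.15, edgeR adjusted p = 3.1e-07). Of 26 genes of the unfolded protein and integrated stress responses 24 rose and 1 fell (the same numbers adjusted over the list alone, median 1.27, camera adjusted p = 1e-10, adjusted p = 0.28 with an estimated correlation). HMOX1 went from 8.56 ± 2.83 to 57.2 ± 21.7 (2.74 ± 0.31, edgeR adjusted p = 6.9e-06). Of 24 oxidative stress genes 19 rose and 1 fell (19 and 1 adjusted over the list alone, median 0.74, camera adjusted p = 3.4e-08, adjusted p = 0.28 with an estimated correlation). The heat shock gene hspa1b rose by 4.61 ± 0.47 (edgeR adjusted p = 2.6e-06). In its list 20 of 26 rose (21 adjusted over the list alone, median 1.89, camera adjusted p = 1.4e-09, adjusted p = 0.43 with an estimated correlation). Of the p53 targets, mdm2 rose by 2.25 ± 0.16 and bbc3 by 1.65 ± 0.14 (edgeR adjusted p = 1.4e-07 and 5.4e-07). Of all 24 of them 17 rose and 2 fell (17 and 2 adjusted over the list alone, median 1.11, camera adjusted p = 1.2e-06, adjusted p = 0.14 with an estimated correlation). The cytokine gene il11a, near 0 in DMSO, rose by 6.99 ± 1.07 and the leptin gene lepb by 8.74 ± 1.22 (edgeR adjusted p = 9.8e-05 and 4.3e-05). The intestinal gene FABP2 went from 410 ± 23.6 to 48.5 ± 16.8 CPM (-3.08 ± 0.21, edgeR adjusted p = 9.9e-08). The blue cone opsin gene opn1sw2 fell by 1.77 ± 0.10 (edgeR adjusted p = 3.3e-08) and the trypsin-like gene prss59.1 by 3.86 ± 0.45 (edgeR adjusted p = 9.4e-06). Photoreceptor genes fell in 38 of 47 (39 adjusted over the list alone, median -0.92, camera adjusted p = 1.2e-14, adjusted p = 0.17 with an estimated correlation). Exocrine pancreas genes fell in 16 of 17 (16 adjusted over the list alone, median -2.45, camera adjusted p = 2.3e-08, adjusted p = 0.49 with an estimated correlation). The 10 most abundant genes took 13.3% to 13.8% of counts at 20000 mg/kg against 11.6% to 12.1% at 1000 mg/kg, a shift that goes with these lists. In all 9864 genes changed between 1000 and 20000 mg/kg of HU, 5170 up and 4694 down, and 2234 in a fit of the libraries of those 2 doses alone. The 3 libraries at 20000 mg/kg lie far apart, with a chi-square per degree of freedom of 34.4, 43.2 and 71.4 between them, where those at each lower dose of HU gave 4.42 to 15.9.

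RA was given at 100 mg/kg only, and 9596 genes changed against DMSO, 4891 up and 4705 down. The cathepsin gene ctsbb went from 60.6 ± 9.77 CPM (n = 6) to 0.619 ± 0.278 (n = 3, log2 -6.67 ± 0.24, edgeR adjusted p = 3e-07), and the pituitary hormone gene prl from 0.0391 ± 0.0702 to 16.1 ± 6.41 (9.17 ± 0.51, edgeR adjusted p = 1.2e-05). HOXB5 (ENSDARG00000054030) rose from 12.7 ± 0.978 to 46.5 ± 4.98 CPM (1.88 ± 0.09, edgeR adjusted p = 4.9e-07), hoxb1b by 2.05 ± 0.14 (edgeR adjusted p = 3.9e-06) and CYP26A1, which breaks down retinoic acid, by 1.14 ± 0.12 (edgeR adjusted p = 5.3e-05). STRA6, a receptor for retinol uptake, fell by 0.98 (edgeR adjusted p = 7.9e-06). Of 28 retinoic acid responsive genes 19 rose and 2 fell (19 and 3 adjusted over the list alone, median 0.56, camera adjusted p = 5.8e-05, adjusted p = 0.15 with an estimated correlation). The lens gene crybb1l3 fell by 4.02 ± 0.23 (edgeR adjusted p = 1.5e-06). Of 40 lens crystallins 39 fell (39 adjusted over the list alone, median -2.21, camera adjusted p = 1.9e-15, adjusted p = 0.45 with an estimated correlation). TOP2A fell from 90.1 ± 13.0 to 37.5 ± 2.37 CPM (-1.26 ± 0.08, edgeR adjusted p = 3e-06). So did 24 of 25 cell cycle genes (24 adjusted over the list alone, median -0.92, camera adjusted p = 3.9e-11, adjusted p = 0.31 with an estimated correlation). INA (ENSDARG00000011862), a neuronal filament gene, fell by 2.16 ± 0.11 (edgeR adjusted p = 8.3e-07). Of 36 neuronal genes 30 fell and 1 rose (31 and 1 adjusted over the list alone, median -0.53, camera adjusted p = 2.6e-10, adjusted p = 0.34 with an estimated correlation). STAT3 rose by 1.73 ± 0.11 (edgeR adjusted p = 2.5e-06). It was among 28 of 33 immune genes that rose (29 adjusted over the list alone, median 1.88, camera adjusted p = 3.6e-09, adjusted p = 0.21 with an estimated correlation). The 10 most abundant genes took 14.6% to 15.7% of counts against 12.4% to 13.4% in DMSO, a shift that goes with these lists. With a single dose, the offset seen at the lowest doses of other codes cannot be set apart here.

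In SXG 5019 genes changed at 20000 mg/kg and 3662 at 250 mg/kg. Between those doses 245 changed, 158 up and 87 down, and 536 with DESeq2. The annexin gene anxa1c went from 49.9 ± 3.36 to 13.8 ± 3.52 CPM (n = 3 and 3, log2 -1.87 ± 0.18, edgeR adjusted p = 5e-05), with DMSO at 67.8 ± 7.77 (n = 6). It was among 6 of 34 epidermis and ionocyte genes that fell (13 down and 2 up adjusted over the list alone, median -0.30, camera adjusted p = 7.5e-08, adjusted p = 0.35 with an estimated correlation). The kinase gene sgk2b rose by 1.00 ± 0.14 (edgeR adjusted p = 0.0015). So did 5 of 19 glucocorticoid responsive genes in all (9 adjusted over the list alone, median 0.51, camera adjusted p = 4.1e-08, adjusted p = 0.35 with an estimated correlation). Against DMSO the median of this list was -0.70 at 250 mg/kg and -0.35 at 20000 mg/kg, so the median rose towards DMSO and not above it. FKBP5 was at 325 ± 51.3 CPM in DMSO, 77.6 ± 27.5 at 250 mg/kg and 233 ± 86.3 at 20000 mg/kg, while sgk2b also rose from DMSO, by 0.82 ± 0.11 (edgeR adjusted p = 3.7e-05). Glycolysis and hypoxia genes rose in 5 of 37 (15 adjusted over the list alone, median 0.23, camera adjusted p = 1.5e-12, adjusted p = 0.14 with an estimated correlation). The 245 rests on single libraries. It became 563, 32 or 78 without replicate 1, 2 or 3 at 20000 mg/kg, 97, 45 or 121 without replicate 1, 2 or 3 at 250 mg/kg, and 116 from the libraries of both doses alone. The 5019 became 3336 without replicate 3 at 20000 mg/kg.

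In Aci 6 and 4 genes changed at 0.0001 and 0.0005 mg/kg (2531 and 2455 at unadjusted p < 0.05) and 3474 at 0.002 mg/kg. With the DMSO 0.005 replicates 4 to 6 left out they became 235, 232 and 4082. Elastase ela2 went from 372 ± 119 CPM in DMSO (n = 9) and 285 ± 52.5 at the lowest dose (n = 3) to 48.7 ± 33.9 at the top dose (n = 3, log2 -2.87 ± 0.42 against DMSO, edgeR adjusted p = 0.00075). From the lowest to the top dose spink4, a trypsin inhibitor gene, fell by 0.76 ± 0.12 (edgeR adjusted p = 0.0017). Exocrine pancreas genes fell in 15 of 17 (16 adjusted over the list alone, median -1.92, camera adjusted p = 3.2e-19, adjusted p = 0.28 with an estimated correlation). The peptide transporter gene SLC15A1 (ENSDARG00000100315) fell by 1.05 ± 0.08 (edgeR adjusted p = 3e-06). Intestine genes fell in 16 of 37 and rose in 2 (20 and 2 adjusted over the list alone, median -0.44, camera adjusted p = 5.1e-12, adjusted p = 0.28 with an estimated correlation). Lens crystallins fell in 21 of 43 (31 adjusted over the list alone, median -0.27, camera adjusted p = 3.6e-18, adjusted p = 0.28 with an estimated correlation). The vasodilator gene ADM (ENSDARG00000069027) rose from 4.30 ± 0.438 to 22.5 ± 5.87 CPM (2.39 ± 0.24, edgeR adjusted p = 4.9e-05). The mitochondrial share of counts moved with these lists, at 3.76% to 3.81% against 3.45% to 3.51%. Between these doses of Aci 1334 genes changed, 719 up and 615 down. The 1334 became 716 or 533 without replicate 2 or 3 at 0.002 mg/kg and 772, 775 or 715 without replicate 1, 2 or 3 at 0.0001 mg/kg. The 3474 became 2048 or 1869 without replicate 2 or 3 at 0.002 mg/kg.

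Mes raised TRPV6, an epithelial calcium channel gene, from 6.65 ± 1.07 CPM at 100 mg/kg to 22.2 ± 1.12 at 5000 mg/kg (n = 3 and 3, log2 1.74 ± 0.15, edgeR adjusted p = 2.2e-06), and fthl29 by 2.14 ± 0.24 (edgeR adjusted p = 3.5e-05). The globin gene hbae1.1 went from 545 ± 209 to 146 ± 25.5 CPM (-1.90 ± 0.24, edgeR adjusted p = 0.00016). Of 22 erythroid genes 12 fell and 1 rose (15 and 1 adjusted over the list alone, median -0.59, camera adjusted p = 6.9e-10, adjusted p = 0.30 with an estimated correlation), from a median of 0.35 above DMSO to -0.34. Genes of the respiratory chain rose in 20 of 26 (24 adjusted over the list alone, median 0.29, camera adjusted p = 3.4e-20, adjusted p = 0.17 with an estimated correlation), CYC1 by 0.41 ± 0.05 (edgeR adjusted p = 0.0001). The mitochondrial share of counts moved with this and the other lists, at 4.05% to 4.20% at 5000 mg/kg against 3.28% to 3.78% at 100 mg/kg. The lens gene CRYAA went from 59.3 ± 5.85 to 29.6 ± 3.39 CPM, a fall of 1.00 ± 0.10 (edgeR adjusted p = 7.5e-06). In all 29 of 43 lens crystallins fell (33 adjusted over the list alone, median -0.38, camera adjusted p = 7.2e-28, adjusted p = 0.17 with an estimated correlation). CYP1A1 rose from 44.9 ± 1.74 to 95.9 ± 18.9 (1.09 ± 0.10, edgeR adjusted p = 3.8e-06). In all 1721 genes changed between those doses of Mes, 844 up and 877 down. The 1721 became 1069 or 885 without replicate 1 or 3 at 5000 mg/kg and 928 without replicate 2 at 100 mg/kg. The 5515 against DMSO became 3551 without replicate 1 at 5000 mg/kg.

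Top moved the same calcium channel gene, TRPV6, from 6.25 ± 0.461 CPM at 100 mg/kg to 45.3 ± 6.13 at 5000 mg/kg (n = 3 and 3, log2 2.86 ± 0.14, edgeR adjusted p = 1.6e-10), a change that differed from that in Mes (Mes minus Top -1.14, edgeR adjusted p = 0.005). The Top libraries at 5000 mg/kg also differ in clock genes (below), and whether this bears on TRPV6 was not tested. The ionocyte transcription factor gene foxi3a went from 6.72 ± 0.881 to 26.7 ± 3.04 (1.99 ± 0.13, edgeR adjusted p = 1.2e-08). The ammonium transporter gene RHCG (ENSDARG00000003203) went from 192 ± 9.83 to 39.1 ± 21.9 (-2.28 ± 0.30, edgeR adjusted p = 0.00014). Epidermis and ionocyte genes rose in 12 of 34 and fell in 4 (13 and 6 adjusted over the list alone, median 0.05, camera adjusted p = 0.0056, adjusted p = 0.46 with an estimated correlation). The embryonic globin gene hbae5 fell by 3.34 ± 0.48 (edgeR adjusted p = 0.00029). The clock gene PER2 was at 18.5 ± 16.6 CPM in DMSO (n = 9), 115 ± 10.3 at 100 mg/kg and 9.94 ± 1.31 at 5000 mg/kg (-3.54 ± 0.60 between the doses, edgeR adjusted p = 0.0013). Against DMSO PER2 did not pass at 5000 mg/kg (-0.47 ± 0.52, edgeR adjusted p = 0.61; 0.35 and 0.038 with the DMSO 0.005 replicates 4 to 6 left out), while the clock gene NR1D1 fell by 1.91 ± 0.08 (edgeR adjusted p = 1.5e-12). From the lowest to the top dose 21 of 33 circadian clock genes fell (25 adjusted over the list alone, median -0.67, camera adjusted p = 1.8e-20, adjusted p = 0.24 with an estimated correlation). Mitochondrial counts moved with these lists, at 3.79% to 3.85% of all at 5000 mg/kg against 3.22% to 3.42% at 100 mg/kg. In all 2297 genes changed between both doses, 1009 up and 1288 down. Lens crystallins fell in 21 of 42 (32 adjusted over the list alone, median -0.23, camera adjusted p = 1.4e-15, adjusted p = 0.28 with an estimated correlation). The 2297 became 1445 without replicate 2 at 5000 mg/kg, 1515 or 1422 without replicate 1 or 2 at 100 mg/kg and 853 from the libraries of both doses alone. The 3743 against DMSO became 2208 or 2448 without replicate 2 or 3 at 5000 mg/kg and 2356 with the 0.01 DMSO libraries alone.

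Fen lowered genes that glucocorticoids induce. FKBP5 stood at 305 ± 40.6 CPM in DMSO (n = 9), 236 ± 46.8 at 1 mg/kg (n = 3) and 25.5 ± 14.7 at 8 mg/kg (n = 3, log2 -3.60 ± 0.32 against DMSO, edgeR adjusted p = 6.4e-06). From the lowest to the top dose PCK1, an enzyme of glucose synthesis, fell from 941 ± 78.7 to 278 ± 97.6 CPM (-1.76 ± 0.23, edgeR adjusted p = 0.00084). Of 19 glucocorticoid responsive genes 9 fell (10 down and 3 up adjusted over the list alone, median -0.35, camera adjusted p = 0.0001, adjusted p = 0.17 with an estimated correlation). POMC, the precursor of the hormone that drives cortisol release, rose from 1.90 ± 0.877 to 16.7 ± 7.88 (3.16 ± 0.44, edgeR adjusted p = 0.0011). The cytochrome gene cyp2k18 went from 20.6 ± 5.30 to 90.1 ± 22.6 CPM (2.14 ± 0.25, edgeR adjusted p = 0.0003). The glutathione transferase gene mgst3b rose by 0.82 ± 0.07 (edgeR adjusted p = 6.2e-06). Of 24 oxidative stress genes 8 rose (13 up and 2 down adjusted over the list alone, median 0.35, camera adjusted p = 1.2e-06, adjusted p = 0.31 with an estimated correlation). Neuronal genes fell in 17 of 36 (29 adjusted over the list alone, median -0.27, camera adjusted p = 1.7e-16, adjusted p = 0.35 with an estimated correlation), from a median of 0.15 above DMSO to -0.11. In all 1358 genes changed between those doses of Fen, 642 up and 716 down, and 2623 with all groups of the prefix in one fit. Replicate 1 at 8 mg/kg of Fen stands apart, with a chi-square per degree of freedom of 16.2 and 17.0 to the other libraries of its group against 4.03 between those. Without it the cytokine gene il1b went from 5.87 to -0.73 and the matrix protease gene mmp13a from 4.54 to -0.08 against DMSO, and MMP9 from 6.01 to -0.17 between the doses. The 1358 became 483 without this library, 423, 816 or 628 without replicate 1, 2 or 3 at 1 mg/kg and 674 from the libraries of both doses alone. The 4377 against DMSO became 2753 without replicate 1 at 8 mg/kg.

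Pro raised genes of foreign-compound and fat metabolism. The cytochrome gene cyp2k18 went from 17.2 ± 4.14 CPM in DMSO (n = 9) to 300 ± 94.0 at 70 mg/kg (n = 3, log2 4.14 ± 0.18, edgeR adjusted p = 1.2e-10), with a rise of 1.64 at 5 mg/kg (edgeR adjusted p = 1.9e-05). From 5 to 70 mg/kg (n = 3 and 3) the glutathione transferase gene gstt1b went from 17.7 ± 3.31 to 70.4 ± 13.8 (1.99 ± 0.16, edgeR adjusted p = 6e-07). ALAS1, the first enzyme of haem synthesis, went from 394 ± 24.6 to 1030 ± 130 CPM (1.38 ± 0.16, edgeR adjusted p = 4.8e-05). Xenobiotic metabolism genes rose in 10 of 27 and fell in 2 (13 and 2 adjusted over the list alone, median 0.43, camera adjusted p = 4e-05, adjusted p = 0.14 with an estimated correlation). The carnitine transferase gene CPT1B rose by 0.66 ± 0.10 (edgeR adjusted p = 0.00053). The fatty acid oxidation list rose with 16 of 30 (19 adjusted over the list alone, median 0.33, camera adjusted p = 3.6e-14), and its call held at adjusted p = 0.0025 with an estimated correlation. Respiratory chain genes rose in 18 of 26 (20 adjusted over the list alone, median 0.27, camera adjusted p = 4.7e-18, adjusted p = 0.17 with an estimated correlation). The carboxypeptidase gene CPA1 (ENSDARG00000030915) fell by 2.88 ± 0.45 (edgeR adjusted p = 0.0007). Exocrine pancreas genes fell in 13 of 17 (16 adjusted over the list alone, median -1.58, camera adjusted p = 4.1e-17, adjusted p = 0.31 with an estimated correlation). The lens gene crygmx fell by 0.62 ± 0.07 (edgeR adjusted p = 1.7e-05). Of 43 crystallins 31 fell (34 adjusted over the list alone, median -0.53, camera adjusted p = 4.5e-32, adjusted p = 0.17 with an estimated correlation). At 70 mg/kg 3.56% to 3.83% of counts were mitochondrial against 3.11% to 3.47% at 5 mg/kg, and the 10 most abundant genes took 11.2% to 11.5% against 10.3% to 11.1%, both moving with these lists. In all 1530 genes changed between those doses of Pro, 969 up and 561 down. The count became 970 or 966 without replicate 2 or 3 at 70 mg/kg, 849 without replicate 1 at 5 mg/kg and 903 from the libraries of both doses alone.

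**Figure D3:**
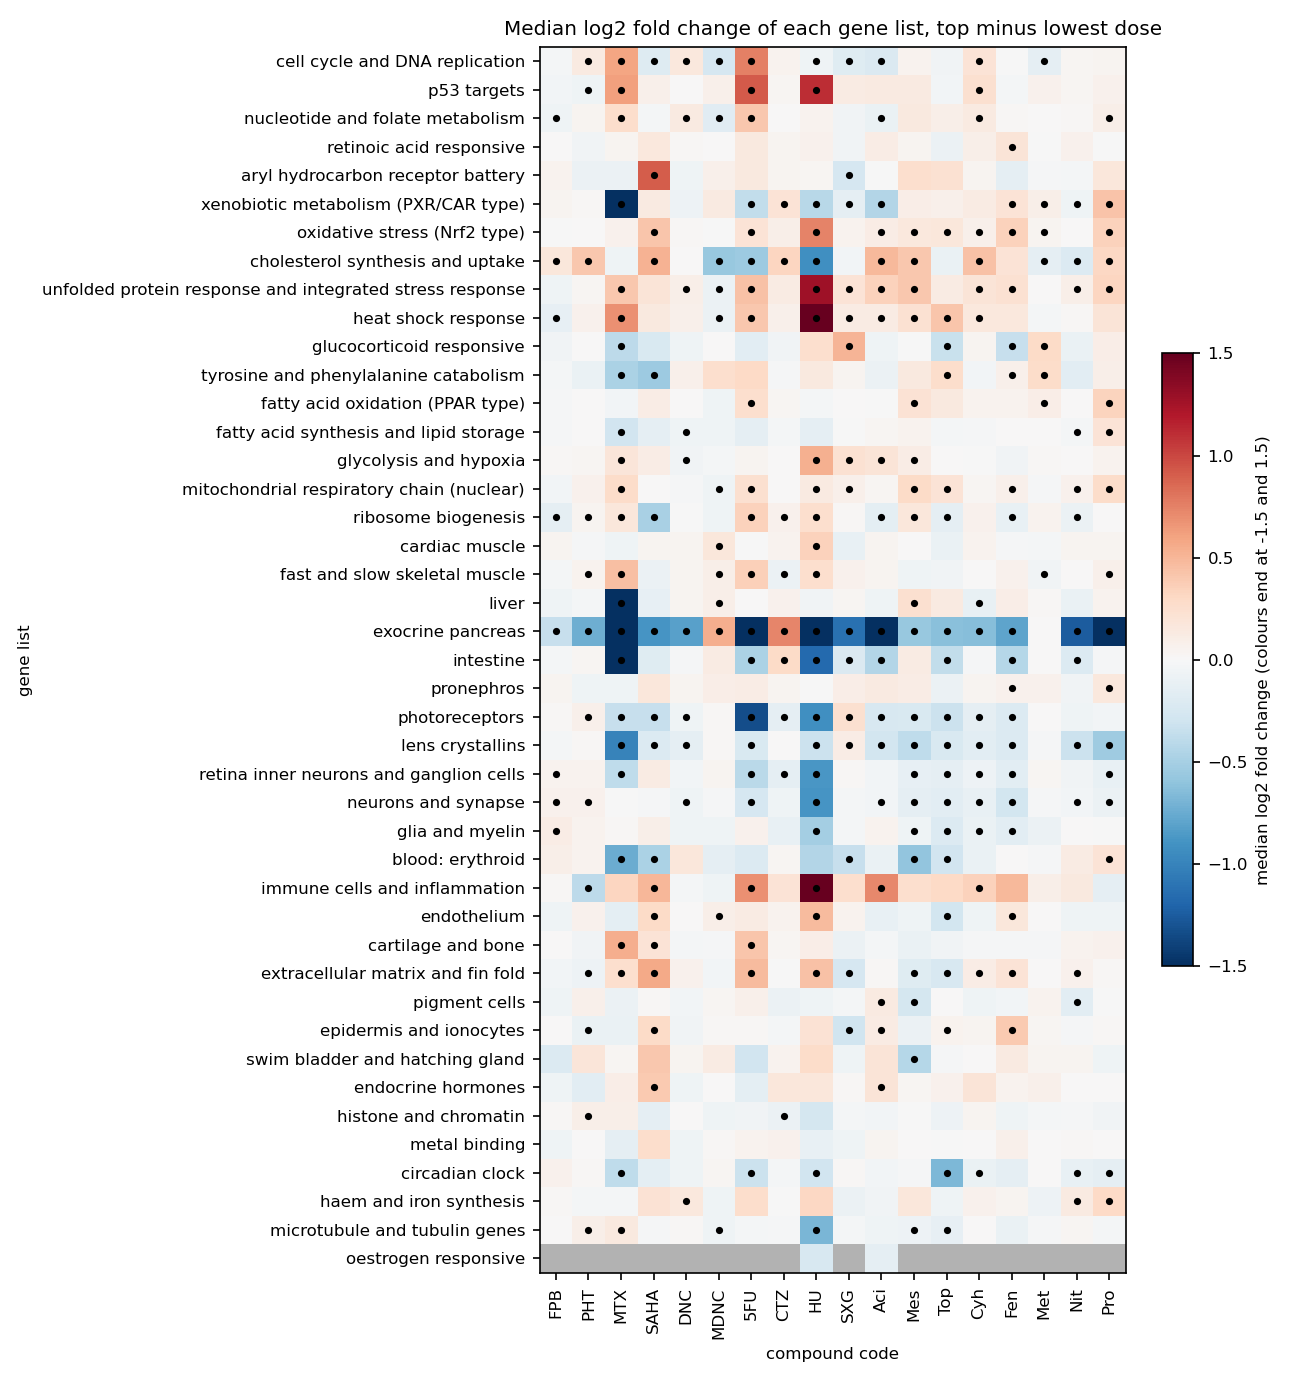
Median log2 change of each gene list between the top and lowest dose of each compound, from -4.80 for the exocrine pancreas in MTX to 2.15 for immune cells and inflammation in HU.

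Met at 200 mg/kg raised gstt1b from 19.3 ± 2.27 CPM at 1 mg/kg to 36.0 ± 2.09 (n = 3 and 3, log2 0.90 ± 0.11, edgeR adjusted p = 0.00038) and the cytochrome gene cyp2y3 by 0.74 ± 0.09 (edgeR adjusted p = 0.00038), among 25 genes that changed between those doses, 24 up and 1 down. Tyrosine breakdown genes rose in 2 of 11 (7 adjusted over the list alone, median 0.27, camera adjusted p = 1.1e-10, adjusted p = 0.079 with an estimated correlation). DESeq2 gave 66 genes in place of the 25. The 25 became 11 or 15 without replicate 2 or 3 at 200 mg/kg and 9, 8 or 8 without replicate 1, 2 or 3 at 1 mg/kg. The 5281 against DMSO became 3428 without replicate 2 at 200 mg/kg. In Nit 4 genes differed between 10 and 80 mg/kg, with 1500 at unadjusted p < 0.05, 79 with DESeq2 and 6 with limma, and all 4 calls ended in 1 or more of the fits without a library. They became 33 without replicate 3 at 80 mg/kg, 0, 1 or 0 without replicate 1, 2 or 3 at 10 mg/kg and 26 with all groups of the prefix in one fit. Of the 42 lens crystallins of Nit 1 fell past the threshold and 28 did so adjusted over the list alone (list called down, median -0.32, camera adjusted p = 5.6e-38, adjusted p = 0.15 with an estimated correlation), while 3.45% to 3.68% of counts were mitochondrial at 80 mg/kg against 3.29% to 3.43% at 10 mg/kg.

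Between the top and lowest dose no gene passed edgeR in FPB (961 at unadjusted p < 0.05, 15 with DESeq2, 1 with limma on the deposited table), PHT (1460, 19 and 0), MDNC (1898, 33 and 0), CTZ (2204, 70 and 1) or Cyh (3165, 246 and 0), and 1 passed in DNC (1590, 36 and 3). In counts simulated for Pro and HU, DESeq2 made 22 and 27 false calls for this contrast and edgeR 7 and 5, and the codes given here were not simulated. In CTZ 266 genes passed without replicate 3 at 100 mg/kg, 1, 2 or 9 without replicate 1, 2 or 3 at 1500 mg/kg and 10 with all groups of the prefix in one fit. In Cyh 5 or 12 passed without replicate 2 or 3 at 4 mg/kg and 28 with all groups in one fit. FPB gave 2 without replicate 1 at 0.1 mg/kg, PHT 1 and 1 without replicate 1 at 80 mg/kg or 3 at 10 mg/kg, and MDNC 1 without replicate 1 at 0.1 mg/kg. For DNC the numbers were 3, 0 or 0 without replicate 1, 2 or 3 at 0.1 mg/kg and 4 or 2 without replicate 2 or 3 at 0.01 mg/kg. Of 25 cholesterol synthesis genes in MDNC 0 passed the threshold and 9 did so adjusted over the list alone (list called down, median -0.57, camera adjusted p = 3.2e-09, adjusted p = 0.40 with an estimated correlation). Of 24 p53 targets in Cyh 0 passed the threshold and 4 did so adjusted over the list alone (list called up, median 0.24, camera adjusted p = 0.0005, adjusted p = 0.32 with an estimated correlation). Against DMSO the DNC count of 7072 became 4653 without replicate 1 at 0.1 mg/kg. CTZ went from 3485 to 1619 without replicate 1 at 1500 mg/kg, 1744 with the 0.005 and 1698 with the 0.01 DMSO libraries alone. Cyh went from 4193 to 2335 or 2658 without replicate 1 or 3 at 4 mg/kg and 2774 with the 0.005 DMSO libraries alone. With the 0.01 DMSO libraries alone PHT went from 6696 to 4160 and MDNC from 6567 to 4209.

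The cell cycle inhibitor gene cdkn1a rose at every dose of HU against DMSO, by 0.52, 0.61, 1.07, 1.22 and 1.06 (each ± 0.11, edgeR adjusted p = 0.047, 0.012, 2.3e-05, 2.2e-06 and 8.6e-07). In 5FU it was lower at 1000, 2000 and 5000 mg/kg, by 0.45 ± 0.10 at the last (edgeR adjusted p = 0.0026), and higher by 0.96 ± 0.09 at 30000 mg/kg (edgeR adjusted p = 2.1e-07). It was lower at every dose of SXG, from -1.43 ± 0.12 to -1.88 ± 0.13 (edgeR adjusted p = 8.8e-08 and 2.6e-09), and of Met, from -0.91 ± 0.11 to -1.26 ± 0.11 (5.8e-06 and 2e-07), with no order by dose. So it was at every dose of PHT, from -0.63 ± 0.13 to -0.95 ± 0.13 (edgeR adjusted p = 0.0016 and 5.9e-05), CTZ, from -0.60 ± 0.12 to -0.94 ± 0.12 (0.011 and 0.00061), Fen, from -0.67 ± 0.10 to -1.20 ± 0.11 (0.00043 and 1.5e-06), Nit, from -0.85 ± 0.13 to -0.94 ± 0.13 (0.00018 and 8.5e-05), and Pro, from -1.03 ± 0.11 to -1.23 ± 0.11 (4.9e-06 and 6.7e-07), and at the only dose of RA (-1.32 ± 0.15, edgeR adjusted p = 0.00012). At the top dose it was also lower in Mes (-0.55 ± 0.11, after -0.26, -0.31 and -0.39 at the lower doses), Top (-1.24 ± 0.15), SAHA (-0.82 ± 0.14) and MDNC (-0.56 ± 0.12, edgeR adjusted p = 0.001, 1.5e-05, 0.00016 and 0.0025). At 0.1 and 0.3 mg/kg of FPB it stood at -0.39 ± 0.13 and -0.41 ± 0.13 (edgeR adjusted p = 0.045 and 0.039). In MTX cdkn1a was higher at 80 and 300 mg/kg, by 1.07 ± 0.22 and 0.60 ± 0.22 (edgeR adjusted p = 0.0017 and 0.036). CYP1A1 rose with dose in Mes, by 0.33 ± 0.08 at 1500 mg/kg and 1.12 ± 0.08 at 5000 mg/kg (edgeR adjusted p = 0.02 and 2.9e-08). In Top it rose by 0.53 ± 0.08, 0.77 ± 0.07 and 0.48 ± 0.07 from 500 mg/kg on (edgeR adjusted p = 0.00063, 4.8e-06 and 0.00019). In MTX it was lower at 20, 40 and 300 mg/kg, at -1.07 ± 0.30, -0.98 ± 0.30 and -2.55 ± 0.34 (edgeR adjusted p = 0.015, 0.022 and 2.4e-05). It was also lower in RA (-1.02 ± 0.13), at 2000 and 5000 mg/kg of 5FU (-0.59 ± 0.19 and -0.72 ± 0.18) and at 50 mg/kg of Met (-0.42 ± 0.08, edgeR adjusted p = 0.00014, 0.036, 0.0077 and 0.001). It was higher at 1000 mg/kg of SAHA (1.43 ± 0.18), 0.01 mg/kg of MDNC (0.58 ± 0.17), and 1 and 4 mg/kg of Fen (0.22 ± 0.07 and 0.23 ± 0.07, edgeR adjusted p = 1.7e-05, 0.027, 0.037 and 0.025). In Pro it rose by 1.09 ± 0.21 at 40 mg/kg and 0.74 ± 0.21 at 70 mg/kg (edgeR adjusted p = 0.00098 and 0.014). CYP26A1 rose at 10, 20, 40 and 80 mg/kg of MTX, by 0.69 ± 0.11, 0.69 ± 0.11, 0.75 ± 0.11 and 0.43 ± 0.12, and stood at -0.14 ± 0.12 at 300 mg/kg (edgeR adjusted p = 0.00044, 0.00031, 0.00013, 0.012 and 0.38). CYP26A1 was lower at every dose of PHT, from -0.34 ± 0.12 to -0.55 ± 0.12 (edgeR adjusted p = 0.032 and 0.0023), and at 500, 1500 and 5000 mg/kg of Mes, at -0.68 ± 0.18, -0.85 ± 0.19 and -0.59 ± 0.18 (0.043, 0.0097 and 0.022). So it was at 5000 mg/kg of Top (-0.97 ± 0.19), 1 mg/kg of Cyh (-0.74 ± 0.20) and 0.1 mg/kg of DNC (-0.35 ± 0.10, edgeR adjusted p = 0.0018, 0.029 and 0.022). Rises were found at 8 mg/kg of Fen (0.71 ± 0.18), 40 mg/kg of Pro (0.97 ± 0.34) and 50 mg/kg of SAHA (0.41 ± 0.13, edgeR adjusted p = 0.011, 0.047 and 0.04). Changes present at the lowest dose, such as cdkn1a in SXG (-1.78) and Met (-1.26), cannot be set apart from the offset there.

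DNC and MDNC were compared at each shared dose, and 35, 66 and 203 genes differed at 0.01, 0.03 and 0.1 mg/kg, with 2126, 2545 and 3351 at unadjusted p < 0.05. The collagen chaperone gene SERPINH1 (ENSDARG00000019949) was at 42.3 ± 3.78 CPM in DNC and 13.2 ± 1.63 in MDNC at 0.1 mg/kg (n = 3 and 3, log2 1.68 ± 0.17, 95% interval 1.33 to 2.03, edgeR adjusted p = 3.7e-05). The gene plekhf1 was lower in DNC by 2.00 ± 0.23 (95% interval -2.49 to -1.52, edgeR adjusted p = 0.00015). The clock gene nr1d4b was lower by 0.85 ± 0.13 (95% interval -1.12 to -0.58, edgeR adjusted p = 0.0022). These gaps were not limited to that dose. At 0.01 and 0.03 mg/kg SERPINH1 stood at 1.00 and 0.81 (edgeR adjusted p = 0.011 and 0.044), nr1d4b was lower by 1.00 and 0.80 (0.0012 and 0.009), and plekhf1 stood at -1.03 and -1.51 (0.097 and 0.011), and no label says whether these codes were handled together. Clock genes were lower in DNC in 9 of 33 (13 lower and 3 higher adjusted over the list alone, median -0.18, camera adjusted p = 5.3e-08, adjusted p = 0.19 with an estimated correlation). Of 25 cholesterol synthesis genes 0 passed the threshold, and 16 were higher and 1 lower in DNC adjusted over the list alone (list called up, median 0.61, camera adjusted p = 5.8e-08, adjusted p = 0.38 with an estimated correlation). Of 17 exocrine pancreas genes 0 passed the threshold and 0 adjusted over the list alone (list called down, median -0.65, camera adjusted p = 2e-06, adjusted p = 0.52 with an estimated correlation). Of 24852 genes tested, 78.7% had an interval within a change of 2-fold either way at 0.1 mg/kg, with a median half-width of 0.33. The change from the lowest to the top dose differed between both codes in 0 genes, with 2273 at unadjusted p < 0.05. The 203, 88 higher and 115 lower, became 105 or 64 without DNC replicate 1 or 2, 78 or 118 without MDNC replicate 2 or 3, and 453 with DESeq2.

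Mes and Top differed by 107, 270, 209 and 3215 genes at 100, 500, 1500 and 5000 mg/kg. At 5000 mg/kg PER2 was higher in Mes (n = 3 and 3, log2 4.06 ± 0.50, 95% interval 3.03 to 5.08, edgeR adjusted p = 6e-06), while at 100, 500 and 1500 mg/kg it did not differ past the threshold (-0.21, -0.33 and -0.15, edgeR adjusted p = 0.90, 0.81 and 0.92). With the DMSO 0.005 replicates 4 to 6 left out, PER2 in Top stood at 3.89, 4.24 and 4.43 from DMSO at those 3 doses and at 0.35 at 5000 mg/kg, and in Mes at 3.67 to 4.41 over all doses. So the difference rests on the Top libraries at 5000 mg/kg alone, for which no label gives an hour or batch of collection. Of 33 clock genes 22 were higher in Mes and 1 lower (24 and 1 adjusted over the list alone, median 0.76, camera adjusted p = 1.7e-24, adjusted p = 0.11 with an estimated correlation). SERPINH1 (ENSDARG00000019949) was lower in Mes by 2.68 ± 0.25 (95% interval -3.18 to -2.17, edgeR adjusted p = 5.7e-08), and by less and not past the threshold at 100, 500 and 1500 mg/kg (-0.49, -0.85 and -0.47). DDB2, a repair gene, was higher by 1.23 ± 0.16 (95% interval 0.91 to 1.56, edgeR adjusted p = 6.7e-06), against -0.55, -0.41 and -0.59 at the lower doses. Epidermis and ionocyte genes were lower in Mes in 12 of 34 and higher in 1 (15 and 2 adjusted over the list alone, median -0.30, camera adjusted p = 5e-07, adjusted p = 0.11 with an estimated correlation). With these lists the mitochondrial share of counts differed, at 4.05% to 4.20% in Mes and 3.79% to 3.85% in Top. Of 25304 genes tested, 77.2% had an interval within a change of 2-fold either way. The 3215, 1515 higher and 1700 lower, became 1978 or 2103 without Mes replicate 1 or 3 and 1864 without Top replicate 2.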

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

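The leaving out of 3 DMSO libraries, the test of the lens list against matched genes, the tests of shared handling, of effects already full at the lowest dose and of a wrong scaling factor were chosen only after the result was seen, and so was the contrast between the top and lowest dose.

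Among the 6 DMSO 0.005 libraries of AM633, replicate 1 stood far from the rest in the heat shock list, with a mean log2 CPM of 4.42 against at most 4.21 in the others, and in the immune list, with 2.46 against 1.54 to 1.76. Replicate 5 was low in the list of fatty acid synthesis and lipid storage, at 4.29 against 4.36 to 4.39. Replicate 3 was high in the list of the swim bladder and hatching gland, at 3.07 against 2.02 to 2.35. Among 47 quantities tested in this way, chance marks about 1 in 20. The change from the lowest to the top dose differed between Mes and Top in 327 genes by a test of the difference itself.

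In 14 compounds over 1000 genes separate the lowest dose from DMSO. Unequal depth is argued against, since after thinning every library of a prefix to the depth of its shallowest the median count was 80.6% of that before (67.2% to 91.5% over the 14). Batches of handling that several compounds share and no label names may account for part of it: of 46 pairs of these compounds, 8 differed from each other by under 5% of the smaller of their counts against DMSO. Effects of the compounds that are full at the lowest dose cannot be told apart from this, since 18 pairs lay under 25% and 20 pairs at 100% or above, and no label gives the day of handling. The design gives no group to test a biological explanation.

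Lens crystallin genes were called lower at the top than at the lowest dose in 12 of 18 compounds by camera at the preset correlation, and in 0 with an estimated correlation after adjustment over all lists and compounds. By edgeR 0 of 41 members passed the threshold in DNC, 0 of 43 in Cyh, 1 of 42 in Nit, 5 of 42 in SAHA and 6 of 43 in 5FU. With each library as the unit and in all 18 compounds whatever their call, the mean of the list fell beyond that of other genes matched on expression in 10, by a log2 of -0.12 in DNC to -0.97 in MTX (adjusted p at most 0.033), while the matched genes moved by at most 0.04. In those 10 this argues against a fall of abundant transcripts in general and a wrong factor of a library, which shifts both sets alike. The 12 list medians lay at percentile 0.21 or lower among 10000 random lists matched on mean expression. They lay at -0.13 or lower from that of all genes, but the call that picked these 12 favours both. RLE size factors moved them by at most 0.02, too little to test scaling, and the deposited values gave -0.12 or lower. In 5FU and Fen the difference did not pass (adjusted p = 0.12 and 0.060). The design gives no group to test a biological explanation.

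Splits of the same libraries were fitted with the DMSO titles pooled. For the top dose against DMSO, only the real split gave as many genes under AL980 (1 of 84 for each of 11 compounds). This excludes chance labels, not handling shared by a group. The real counts and the highest of the others were 3366 and 27 for FPB, 5665 and 34 for PHT, 9254 and 2 for MTX, 9930 and 3 for SAHA, 5627 and 16 for DNC, 5036 and 37 for MDNC, 10486 and 1 for 5FU, 3462 and 2 for CTZ, 9654 and 1 for HU, 9464 and 1 for RA, and 3909 and 2 for SXG. Under AM633 100 of 220 splits were drawn, with the same outcome and limit (1 of 100 for each of 8 compounds). There they were 2785 and 5 for Aci, 5131 and 2 for Mes, 3485 and 13 for Top, 3275 and 488 for Cyh, 3516 and 5 for Fen, 4329 and 3 for Met, 5735 and 2 for Nit, and 7012 and 3 for Pro.

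Between the top and lowest dose 3 libraries against 3 make 10 splits, too few for a share under 0.05. In fits of those libraries alone the real counts and the highest of the others were 1019 and 1 for MTX, 3673 and 0 for SAHA, 5765 and 0 for 5FU, 2234 and 0 for HU, 116 and 0 for SXG, 1268 and 1 for Aci, 1732 and 1 for Mes, 853 and 0 for Top, 674 and 1 for Fen, 32 and 2 for Met, 903 and 1 for Pro, and 10 and 1 for MDNC. They were 1 and 16 for FPB, where 8 of the 10 gave as many, 3 and 13 for PHT with 3 of the 10, and 9 and 16 for DNC with 2 of the 10. For CTZ, Cyh and Nit edgeR gave 0 and the others at most 1, 2 and 2, where 10 of the 10 gave as many, as any split must. In the full fits these 3 had 2204, 3165 and 1500 genes at unadjusted p < 0.05, and 70, 246 and 79 with DESeq2. The pairs of compounds and the DMSO titles of AL980 have 10 splits as well, with 45 and 9 for DNC against MDNC, 2466 and 0 for Mes against Top, and 44 and 2 for the DMSO titles.

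The DMSO titles of AM633 differed by 2 genes, and 4 of the 84 splits of those 9 libraries gave as many. Another of these splits, 0.005 replicates 4 to 6 against the other 6, gave 1346, which points to a structure of the samples. The titles give these 3 only their replicate numbers, and no label names a batch. PER2 was 31.6 to 47.2 CPM in them and at most 8.27 in the other 6. With these 3 left out the 6 genes at the lowest dose of Aci became 235, and the 369 of Mes became 1078, so that 15 compounds have over 1000 genes there. For the difference of the title contrast between the prefixes, where edgeR gave 0 (2393 at unadjusted p < 0.05, 145 with DESeq2), the highest of the other splits was 46. That 100 of 100 gave as many follows from the count of 0 and decides nothing about chance.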

How the results depend on the processing

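The contrast of top minus lowest dose, with each of its alternatives, the use of the lowest dose in place of DMSO and the leaving out of the DMSO 0.005 replicates 4 to 6 of AM633 were chosen after the data were seen. All other alternatives were planned. Of 43 counts of changed genes, RLE size factors moved 0 by over 1.5 times, no filter 1, the replicate block 4, limma on the deposited values 5, all groups of a prefix in one fit 5 of 38, the top dose and its reference libraries only 12 of 38, and DESeq2 13. Of 849 other counts, at lower doses and of list members, the DMSO 0.01 libraries alone moved 226, the DMSO 0.005 libraries alone 173, the replicate block 56, DESeq2 38, no filter 25, limma 16 and RLE 1. Of 798 of them all groups of a prefix in one fit moved 118, and the top dose and its reference libraries only 96. For each count below that an alternative moved, the cause was not tested, except that fits with fewer libraries estimate the spread from fewer of them. The log2 values of limma are smaller for genes with low counts, since the deposited table is variance-stabilised. Depth, from 8.22 M reads in the shallowest library, limits what can be said of genes with few counts, and genes that the filter dropped were not tested.

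With DESeq2 the counts between the top and lowest dose were 15 for FPB (0 with edgeR), 19 for PHT (0), 36 for DNC (1), 33 for MDNC (0), 70 for CTZ (0), 536 for SXG (245), 246 for Cyh (0), 66 for Met (25) and 79 for Nit (4). Between DNC and MDNC at 0.1 mg/kg DESeq2 gave 453 (203), between the DMSO titles 264 under AL980 (44) and 100 under AM633 (2), and 145 for the difference of that contrast between the prefixes (0). In limma on the deposited table the counts between the top and lowest dose were 1 for FPB, 3 for DNC and 1 for CTZ, and those between the DMSO titles 18 under AL980 and 1 under AM633. In edgeR with no filter on low counts, the count between the DMSO titles of AM633 was 1.

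Fits of the top dose and its reference libraries only gave, between the top and lowest dose, 1 for FPB, 3 for PHT, 1019 for MTX (4009 in the full fit), 3673 for SAHA (6299), 9 for DNC, 10 for MDNC, 2234 for HU (9864), 116 for SXG, 853 for Top (2297), 674 for Fen (1358), 0 for Nit (4, with 1500 at unadjusted p < 0.05 in the full edgeR fit and 79 with DESeq2) and 903 for Pro (1530). With all groups of a prefix in one fit the counts were 0 for DNC, 10 for CTZ, 28 for Cyh, 2623 for Fen and 26 for Nit.

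With only the DMSO 0.01 libraries the counts at the top dose were 1545 for FPB (3628), 4160 for PHT (6696), 4209 for MDNC (6567), 1698 for CTZ (3485) and 2356 for Top (3743). With only the DMSO 0.005 libraries they were 1744 for CTZ and 2774 for Cyh (4193). With the lowest dose in place of DMSO they were 0 for FPB, PHT, MDNC, CTZ and Cyh, 1 for DNC, 4 for Nit, 25 for Met, 245 for SXG, 1334 for Aci, 1358 for Fen, 1530 for Pro, 1721 for Mes, 2297 for Top, 4009 for MTX, 6215 for 5FU and 6299 for SAHA. At unadjusted p < 0.05 edgeR gave 961 for FPB, 1460 for PHT, 1898 for MDNC, 2204 for CTZ and 3165 for Cyh in place of those 0.

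With the DMSO 0.005 replicates 4 to 6 of AM633 left out, 2 of 18 counts moved by over 1.5 times, from 2 to 0 between the DMSO titles of AM633 (1914 and 1633 at unadjusted p < 0.05, 100 with DESeq2 and 1 with limma on all libraries) and from 0 to 1 for the difference between the prefixes. Of 20 counts at lower doses 8 moved, from 6 to 235 and 4 to 232 for Aci at 0.0001 and 0.0005 mg/kg, 369 to 1078 and 811 to 1732 for Mes at 100 and 500 mg/kg, 184 to 560, 729 to 1189 and 1174 to 2003 for Top at 100, 500 and 1500 mg/kg, and 2034 to 3057 for Cyh at 1 mg/kg.

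Over all pairs of groups of a prefix, most of them of different compounds, the mean correlation between libraries with the same replicate number was -0.00082 under AL980 and 0.00015 under AM633. Sharing within the doses of 1 compound or between the DMSO groups was not tested apart. With the replicate block the counts were 0 for DNC between the top and lowest dose, 10 and 0 between the DMSO titles under AL980 and AM633, and 1 for the difference between the prefixes. The other 39 of the 43 stayed within 1.5 times.

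With an estimated correlation 0 of 373 list calls at the top dose and 2 of 285 between the doses passed.

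Leaving out each library in turn moved 90 of 345 counts by over 1.5 times. The lowest and highest counts at the top dose were 1695 and 3294 for FPB, 4653 and 6815 for DNC, 1619 and 2853 for CTZ, 3336 and 4783 for SXG, 1869 and 3811 for Aci, 3551 and 5782 for Mes, 2208 and 4088 for Top, 2335 and 4643 for Cyh, 2753 and 4671 for Fen, and 3428 and 5319 for Met. Between the top and lowest dose they were 0 and 2 for FPB, 0 and 1 for PHT, 4053 and 7327 for SAHA, 0 and 4 for DNC, 0 and 1 for MDNC, 4079 and 5578 for 5FU, 0 and 266 for CTZ, 32 and 563 for SXG, 533 and 1262 for Aci, 885 and 1336 for Mes, 1422 and 2509 for Top, 0 and 12 for Cyh, 423 and 1404 for Fen, 8 and 20 for Met, 0 and 33 for Nit, and 849 and 1331 for Pro. They were 64 and 151 for DNC against MDNC, 1864 and 2420 for Mes against Top, 0 and 33 between the DMSO titles under AL980, 0 and 4 under AM633, and 0 and 15 for the difference between the prefixes.

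Of the changes of named genes 6 turned direction. HMOX1 in PHT against DMSO stood at -0.01 with the DMSO 0.01 libraries only, where all libraries gave 0.66. Without replicate 1 at 20000 mg/kg of SXG, POMC went from 1.59 to -0.24, and the highest value without another library was 2.09. Without replicate 1 at 8 mg/kg of Fen, il1b went from 5.87 to -0.73, mmp13a from 4.54 to -0.08 and TIMP2 (ENSDARG00000075261) from 2.54 to -0.20 against DMSO, and MMP9 from 6.01 to -0.17 between the doses. Their highest values without another library were 6.46, 5.11, 3.06 and 6.60. The other 3352 kept their call in every alternative that was run for them, and 1263 lost it in 1 or more, where the size of the change was not compared. Not all were run for each of them, with DESeq2 for 4598, all groups of a prefix in one fit for 4450, and the DMSO 0.005 libraries alone for 3091.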

Other observations

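The leaving out of 3 DMSO libraries, the test of the clock list at the lowest doses, the counts over compounds and the contrast between the top and lowest dose were chosen only after the result was seen.

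Exocrine pancreas genes were called lower at the top than at the lowest dose in 15 of 18 compounds and higher in 2, by camera with the preset correlation. With an estimated correlation 2 of all 285 list calls held after adjustment, p53 targets in 5FU and fatty acid oxidation in Pro. So these tallies rest on the preset value. At the preset correlation photoreceptor genes were called lower in 11 and higher in 2, neuronal genes lower in 10 and higher in 2, and intestine genes lower in 8 and higher in 1. Higher and lower calls numbered 10 and 0 for oxidative stress and 11 and 1 for the unfolded protein and integrated stress responses. They numbered 9 and 1 for the respiratory chain and 4 and 1 for p53 targets. Some calls come from compounds with no list member past the threshold. With the correlation estimated and before adjustment, the pancreas list was lower in 6, photoreceptors in 4, neurons in 1 and intestine in 3. The oxidative stress list was higher in 8, the unfolded protein and integrated stress list in 6, the respiratory chain list in 4 and p53 targets in 3.

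In MTX skeletal muscle genes rose in 24 of 42 between the lowest and the top dose (27 adjusted over the list alone, median 0.45, camera adjusted p = 2.5e-14, adjusted p = 0.28 with an estimated correlation), while liver genes fell in 17 of 32 (22 adjusted over the list alone, median -1.81, camera adjusted p = 1.1e-11, adjusted p = 0.49 with an estimated correlation). In HU immune genes rose in 21 of 33 and fell in 2 (median 2.15, camera adjusted p = 1.2e-05, adjusted p = 0.50 with an estimated correlation), and cholesterol synthesis genes fell in 17 of 25 and rose in 1 (median -0.92, camera adjusted p = 0.00012, adjusted p = 0.51 with an estimated correlation). In RA cholesterol synthesis genes rose in 20 of 25 against DMSO (23 adjusted over the list alone, median 0.81, camera adjusted p = 2.7e-07, adjusted p = 0.37 with an estimated correlation).

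A hypothesis is that time of day or light before collection may have differed between many compound groups and the DMSO libraries. The circadian clock list was among the 3 lists with the largest share of changed members in 11 of the 14 compounds with over 1000 genes at the lowest dose, and first in 4 of them. In PHT 28 of its 33 members changed at the lowest dose (84.8%, against a median of 43.1% over all lists), and in CTZ 60.6% against 6.90%. PER2 was higher than in DMSO at the lowest dose of each of these 14, from 0.69 ± 0.11 in CTZ to 4.61 ± 0.09 in SXG (edgeR adjusted p = 0.0036 and 1.8e-17). It was also higher at the lowest dose of HU (1.73 ± 0.11), Mes (2.84 ± 0.43) and Top (3.07 ± 0.42, edgeR adjusted p = 1.3e-07, 0.0035 and 0.0021), where 127, 369 and 184 genes changed, so its rise does not go only with counts over 1000. In PHT 24 members fell and 4 rose, while in Fen 3 fell and 17 rose, so the direction differed. By camera with an estimated correlation no adjusted p lay under 0.48, and the list came only 12th in MTX, 11th in MDNC and 4th in DNC. At the preset value the clock list was called up in 5 of 18 compounds and down in 6, and ribosome biogenesis up in 17 and down in 0. So the offset holds more than clock genes. Under AM633 PER2 was 31.6 to 47.2 CPM in the DMSO 0.005 replicates 4 to 6 and at most 8.27 in the other 6. The clock gene NR1D1 did not separate them, at 443 to 498 CPM in those 3 and 453 to 505 in the other 6. With those 3 left out PER2 was higher at the lowest dose of every AM633 compound, from 1.75 in Aci to 5.41 in Nit (edgeR adjusted p = 2e-07 and 1.6e-18). An effect of the compounds on the clock itself was not tested and stays open, since no label gives the hour of collection.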
